A study of Mus musculus with 12 samples.

How the data were processed

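Gene expression was measured in mammary tumours of 6 mouse strains that carry an activated neu (ErbB2) transgene under the MMTV promoter. The parental strain is NDL2-5, written NDL25 in the sample names, and the strains NYPD, YB, YC, YD and YE carry altered receptors. Per the labels, RNA of 10 tumours per strain was combined into 2 pools of 5 tumours each, from mice that had borne tumours for 6 weeks, and 500 ng of each pool was amplified in 1 round. Each of the 12 pools was hybridised with Universal Mouse Reference RNA, a commercial mixture of RNA from many mouse cell types, on 2 Agilent arrays with the dyes exchanged, which gave 24 arrays.

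The scanner files hold mean spot intensity and median local background intensity in each channel, per the file headers, and were written by Agilent Feature Extraction. They also hold processed intensity, from which the scanner software had subtracted a fitted background surface and removed a dye difference, and a log10 ratio of the red over the green processed signal, per the file headers. The authors also deposited 1 log2 ratio per dye-swap pair and probe. The submitters' processing notes name RMA, limma and R 2.3.0 for these values. Their exact normalization is not given in the sources used here. Their direction was settled by comparison: across genes, each sample's deposited ratios correlated with the tumour-over-reference ratios computed from its scanner files at r = 0.907 or above. The medians of the deposited ratios ran from -0.00222 to 0.0147. Neither measure shows the base of the logarithm, so reading the deposited values as log2 is an assumption. Between 0.491% and 3.29% of the probes had no deposited value in a sample.

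The labels give Cy3 or Cy5 for both channels, so the dye of the tumour RNA was read from marker genes. On every array 53 probes for luminal and milk genes and 16 probes for genes of liver, testis, muscle and embryonic cells were compared, and all 12 samples had 1 array of each dye. Csn2 and Lalba pointed to the tumour channel and Afp to the reference channel on all 24 arrays. The 16 probes as a set gave no direction, with medians from -0.210 to 0.237 as log2 red over green, both in YB pool 2. There they leaned to the tumour channel. The direction therefore rests on the luminal and milk genes, with Afp as a single gene from the other set. The 2 arrays of a pair correlated at r = -0.818 or below before turning. The tumour was in Cy3 on the first array of 9 samples and in Cy5 on that of 3. Every ratio below is tumour over reference on that basis.

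Intensities were background-corrected by normexp with an offset of 50 and normalised by loess within each array in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8). Spots marked as non-uniform or as outliers were left out, the array with exchanged dyes was turned, and the pair was averaged into 1 log2 ratio per pool. Of 41174 probes, 698 were left out for such marks, 312 because they were well above background in the tumour channel on fewer than 4 arrays, and 11813 because another probe of the same gene was brighter. This left 28351 genes, 17780 of them with ordinary symbols. Probes took current symbols by accession for 20716 and by symbol or synonym for 5039 and 5279, and 10140 kept the name in the file. No genome build or position is given in the sources used here.

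One limma model with a mean for each of the 6 strains was fitted to the 12 pools. It had 6 residual degrees of freedom plus 1.76 from the prior. An F test over the strains and 9 contrasts were run, 5 against NDL25 and 4 against NYPD, with Benjamini-Hochberg adjustment in each and a threshold of 0.05. SE is the moderated standard error of a log2 difference, with n = 2 pools in each strain, and its median over genes was 0.109. Camera with a preset correlation of 0.01 compared 28 fixed gene lists with all other genes in the 9 contrasts, 252 tests adjusted together, and was repeated with an estimated correlation. The similarity of pools was tested exactly over all ways to pair the 12 pools.

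The contrasts, the filters, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls against NDL25, or 5 of each against NYPD, among genes with adjusted p under 0.05, a log2 difference of at least 1, both pools on the same side, signal above background and an ordinary symbol. It adds Erbb2, the 10 smallest p of the F test, bounds for genes at background in 1 strain, and up to 4 members of each list with the smallest p. Where a gene had several probes, disagreement is stated. The model was tested on simulated data with the layout of the YB comparison. It recovered 77 of 100 genes moved by a log2 of 1 and 98 of 100 moved by 2, with 10 false calls. It made 0 list calls when nothing was moved, but the simulated genes varied independently. That count therefore does not test the list calls for genes that vary together.

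The scan records place the arrays in 3 feature extraction sessions. Session 1 held 9 arrays, those of YD and YE and the first array of YC pool 2; session 2 held 11, those of NDL25, YB and the rest of YC; and session 3 held the 4 arrays of NYPD alone. Session was therefore fitted as a block for the contrasts of YB, YC, YD and YE with NDL25. YC pool 2 alone ties sessions 1 and 2, so the blocked YC contrast is that of YC pool 1, and the blocked YD and YE contrasts carry 2 times the difference between YC pools 1 and 2. No block could be fitted for contrasts with NYPD. Alternatives tried were other background corrections, offsets, normalizations, filters, probe choices, variance models, single arrays of a pair, pool number or session as a block, the deposited ratios, only the 2 strains compared, and leaving out each pool. With 1 pool left out, the remaining pool of that strain is assumed to vary like the pools of the other strains.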

Results

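The data were two-colour array measurements of 12 tumour pools, 2 for each of the strains NDL25, NYPD, YB, YC, YD and YE. As background, the NYPD receptor lacks the tyrosine autophosphorylation sites in the tail of ErbB2, and YB, YC, YD and YE each carry 1 of these sites on that background. The comparisons ask how tumours driven by each receptor differ from those of the parental strain and from those driven by the receptor without the sites. Across the 24 arrays the median tumour signal was 364.8 to 763.5 intensity units over a local background of 39 to 64. Between 97.28% and 98.86% of the spots were well above background, and 58 to 360 spots per array were saturated. The number of pools limits the precision.

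Erbb2, the gene of the transgene, was far above the reference in every strain on its brightest probe. The mean log2 ratio was 2.78 ± 1.61 (SD, n = 2) in NDL25, 3.02 ± 1.65 in YB, 3.81 ± 0.13 in YC, 3.76 ± 0.30 in YD, 3.67 ± 0.36 in YE and 4.0 ± 0.07 in NYPD. No Erbb2 contrast passed the test, with adjusted p from 0.548 to 0.965. The spread came from NDL25 pool 1 at 1.65 against 3.92 in pool 2, and from YB pool 1 at 1.85 against 4.19 in pool 2. Another 2 Erbb2 probes gave strain means of 0.12 to 0.30 and 0.56 to 0.92 and did not show this gap. Probe sequences were not available, so which of these probes read the transgene could not be checked. No probe is therefore taken as a measure of transgene expression.

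By the F test 902 genes of 28351 differed among the strains, against 6045 at an unadjusted p under 0.05. Session was not fitted in this test, and most strains lie within a single session, so it does not separate strain from session. The 10 genes with ordinary symbols and the smallest p were Prpmp5, Crisp1, Bpifb1, Pax9, Pitx1, Cldn22, Sbp, Slc2a5, Prb1 and Prp2, all with their highest mean in YB. Prpmp5, which encodes a salivary proline-rich protein, had a mean log2 ratio of 6.04 ± 0.09 (SD, n = 2) in YB and of 0.03 to 0.38 in the other strains. Pitx1, a homeobox gene of oral and hindlimb development, had 2.93 ± 0.30 in YB and -0.25 to -0.17 elsewhere. The count moved both ways when 1 pool was left out. It fell without either pool of NDL25, YC, YD or YE and without NYPD pool 2, and rose without YB pool 1. Such a fit leaves 1 pool in a strain and less to estimate the spread, so a fall does not show that the genes rest on that pool.

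Pools of a strain resembled each other, though unevenly. The mean correlation across genes between the 2 pools of a strain, on values centred per gene, was r = 0.233 (exact one-sided p = 0.00154), and 16 pairings, the real one included, reached it. Genes are not independent replicates. The pools of NDL25 and YB were read in session 2, those of YD and YE in session 1 and those of NYPD in session 3. A shared session may therefore add to the likeness within a strain, and the test does not separate the 2. The correlation was 0.37 in NDL25, 0.33 in YE, 0.29 in YB, 0.23 in NYPD, 0.15 in YC and 0.05 in YD. YC, YD and YE were the exception: their pools 1 correlated with each other at 0.53 for YC and YD, 0.42 for YC and YE and 0.43 for YD and YE, above the values within these strains, and pool 2 of YC correlated with pool 2 of YD at 0.53. Pool 2 of YE had -0.14 with that of YC and -0.05 with that of YD. The pairing that joins the YC and YD pools of the same number gave the highest mean, 0.377.

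NYPD tumours against NDL25 tumours showed higher Saa2, Wap, Glycam1 and Mfge8 and lower Col7a1, S100b and Egf. Saa2, an acute phase serum amyloid, rose 7.98-fold (log2 3.0 ± 0.43 SE, n = 2 pools per strain, adjusted p = 0.0318). The milk genes Wap, Glycam1 and Mfge8 rose 5.02-fold (log2 2.33 ± 0.37), 5.00-fold (2.32 ± 0.36) and 3.82-fold (1.94 ± 0.33). Fads1, a fatty acid desaturase, rose 4.85-fold (2.28 ± 0.34) and Cd14, a co-receptor for bacterial lipopolysaccharide, 4.71-fold (2.24 ± 0.27). Lcn10, Krt79 and Apobr rose by log2 2.14, 1.90 and 1.88. Fgfr1 rose by 2.0 on its brightest probe, while its other 3 probes gave -0.02 to 1.80.

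Col7a1, the collagen of anchoring fibrils, fell by 2.58 ± 0.44 on the log2 scale (adjusted p = 0.0464). Slc6a2, the noradrenaline transporter, fell by 2.13 ± 0.29, S100b by 2.09 ± 0.22 and Egf, a growth factor of the EGF receptor, by 1.68 ± 0.29. Hbb-y and Oas1f changed by -1.63 and -1.42. Eya1, Lnx1, Rab26 and Stard13 also fell, by -1.64, -1.55, -1.48 and -1.44 on their brightest probes, but other probes of the same genes gave -0.11, -1.16 to 0.02, -0.02 and -0.16.

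By list, 5 of 13 milk secretion genes rose, among them Ltf by log2 1.76 and Btn1a1 by 1.59, with 6 higher adjusted over the list alone; the list's median was 0.57 (camera adjusted p = 7.57e-05). The mesenchymal transition list had a median of 0.63 (adjusted p = 1.67e-07) and the fibroblast and matrix list 0.58 (4e-06), but 0 of their 17 and 21 members passed limma over all genes, against 7 and 2 higher adjusted over the list alone. Zeb2, a repressor of E-cadherin, had 0.56 ± 0.12 (adjusted p = 0.0718) and Fn1, fibronectin, 1.10 ± 0.22 (0.0698). Of 14 basal and myoepithelial genes 2 rose, over all genes and adjusted over the list alone: Trp63 by 1.60, with 0.21 on another probe, and Oxtr, the oxytocin receptor, by 1.11, with 0.03 on another (median 0.38, adjusted p = 0.000626). The interferon response list lay lower, with a median of -0.92 (adjusted p = 0.000121), and 1 of 20 members, Oas1a, fell by 1.24, also adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.514 for milk, mesenchymal and basal genes, adjusted p = 0.549 for fibroblasts and adjusted p = 0.647 for interferon. Without NYPD pool 2 the interferon median was -0.50 (adjusted p = 0.156). Of 16 macrophage genes 1 rose, Cd14, with 3 higher adjusted over the list alone (median 0.29, adjusted p = 0.0048, and adjusted p = 0.659 with an estimated correlation).

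**Figure D1:**
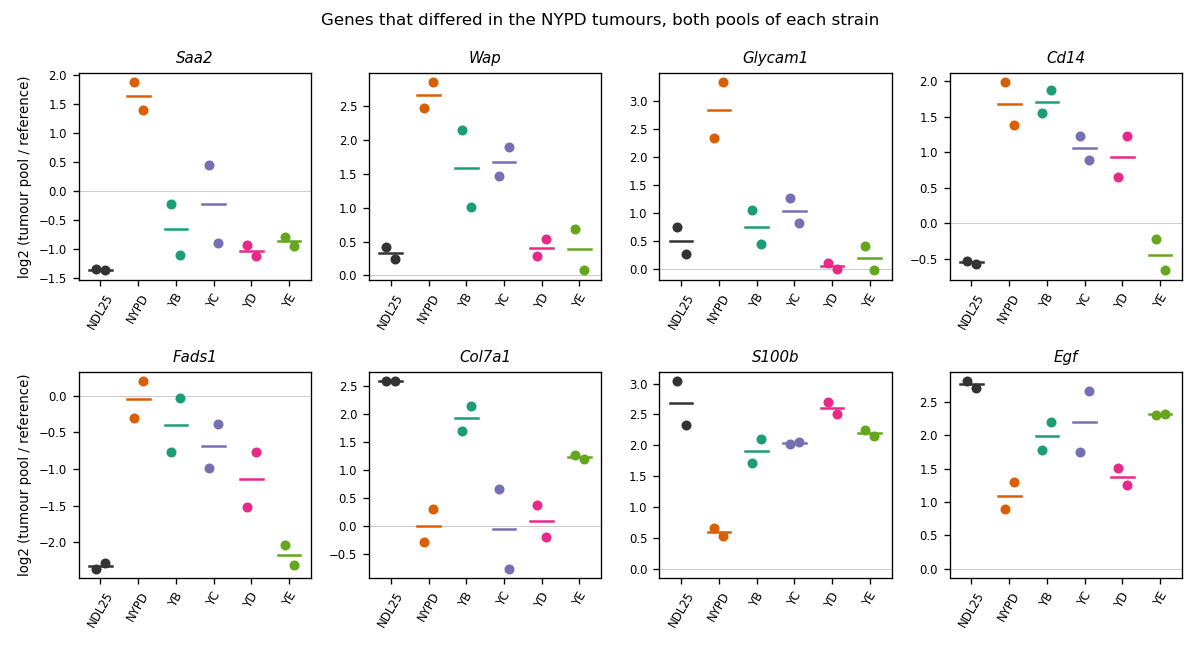
Log2 ratio of tumour pool over reference RNA (y axis) for 8 genes that differed between NYPD and NDL25, in each of the 6 strains (x axis); points are the 2 pools of a strain and lines their mean. Saa2 rose by log2 3.0 in NYPD and Col7a1 fell by 2.58 on the log2 scale.

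Between NYPD and NDL25, 282 genes passed limma, 127 higher and 155 lower in NYPD, and 4443 had an unadjusted p under 0.05. The count was 0 without NDL25 pool 1, 5 without NDL25 pool 2, 583 without either YB pool, 149 without either YC pool, 69 without either YD pool, 144 without either YE pool, 446 without NYPD pool 1 and 168 without NYPD pool 2, and 0 genes were called in every one of these fits. The balance turned as well, with 322 higher and 261 lower without either YB pool, 323 and 123 without NYPD pool 1, and 102 and 66 without NYPD pool 2. All NYPD arrays formed an extraction session of their own, so strain and session cannot be told apart in any contrast with NYPD, and the count was 12 with the pools numbered 1 of NDL25 and YB left out, a choice made after the data were seen.

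YB tumours against NDL25 tumours carried a set of genes that were near or below the reference level in all other strains. Prpmp5 rose 61.7-fold (log2 5.95 ± 0.07 SE, n = 2 pools per strain, adjusted p = 2.17e-08) and Crisp1, a secreted cysteine-rich protein of epididymis and salivary gland, 39.0-fold (5.29 ± 0.07). The salivary proline-rich protein genes Prb1, Prp2 and Prh1 rose 16.6-fold, 14.3-fold and 14.2-fold (4.05 ± 0.18, 3.84 ± 0.17 and 3.83 ± 0.49). Pax9, a transcription factor of pharyngeal and tooth development, rose 16.0-fold (4.0 ± 0.10), and the homeobox gene Meis2 14.5-fold (3.86 ± 0.23, with 2.97 on another probe). Dnase1, a secreted nuclease, and Bpifb1, a secreted protein of airway and oral epithelium, rose 14.2-fold and 12.7-fold. Crisp1 was saturated on 1 of the 4 YB arrays, and Prb1, Prp2, Dnase1 and Bpifb1 on 2, and a saturated spot reads too low. The probe annotated Ubr4 gave 3.62, but another probe of that gene 0.05. Svopl, at background in NDL25, was at least 2.25-fold higher in YB.

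Slc6a2 fell in YB by 1.85 ± 0.29 on the log2 scale (adjusted p = 0.0176), Derl3, a component of endoplasmic reticulum-associated degradation, by 1.72 ± 0.27, and Traf1, an adaptor of TNF receptors, by 1.53 ± 0.22. Cdr2, Tmem82, C5ar2, St6galnac4, Ddo and Proser1 changed by -1.54, -1.52, -1.39, -1.35, -1.35 and -2.0. Eya1 had -1.66 on its brightest probe and -0.18 on the other. With session as a block Proser1, Tmem82, C5ar2, Ddo and Eya1 no longer passed limma (adjusted p = 0.0886, 0.0942, 0.0653, 0.07 and 0.0552). Slc6a2, Derl3, Cdr2, Traf1 and St6galnac4 still passed.

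By list, the proliferation genes lay lower in YB, with a median of -0.43 over 26 genes (camera adjusted p = 2.44e-08); 2 fell over all genes, Tyms by 0.77 and Ttk, a mitotic kinase, by 0.62, and 10 were lower adjusted over the list alone. One of 2 other Tyms probes gave 0.04. Chemokine and cytokine genes had a median of 0.42 (adjusted p = 1.23e-05), and 2 of 22 rose, Cxcl12 by 3.01 and Ccl20 by 2.87, with 4 higher adjusted over the list alone. The macrophage list had 0.53 (adjusted p = 1.46e-05), with Cd14 up by 2.26 as the 1 member of 16 that rose, also adjusted over the list alone. The fibroblast and matrix list had the median 0.75 (adjusted p = 4.81e-06) with 0 of 21 members passing limma, over all genes and adjusted over the list alone. Of 19 squamous genes 3 rose, over all genes and adjusted over the list alone: Tgm3, an epidermal transglutaminase, by 2.48, and Lor and Calml3 by 0.69 and 0.83 (list adjusted p = 0.0424). The squamous list lost its call in 12 of 30 alternative settings. Lor and Calml3 lost theirs in 18 and 20 of 31, and Tgm3 in 0 of 31. The interferon list had -0.70 (adjusted p = 0.00148) with 0 of 20 passing, over all genes and adjusted over the list alone. With an estimated correlation the lists had adjusted p = 0.514 for proliferation, chemokines and macrophages, adjusted p = 0.549 for fibroblasts and adjusted p = 0.659 for squamous and interferon genes. With session as a block Ccl20, Ttk, Lor and Calml3 no longer passed limma (adjusted p = 0.0639, 0.12, 0.121 and 0.108), while Cxcl12, Tyms, Cd14 and Tgm3 did. Without YB pool 1 the medians were 0.15 for macrophages, 0.004 for squamous and -0.49 for interferon genes (adjusted p = 0.069, 0.0933 and 0.0818).

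**Figure D2:**
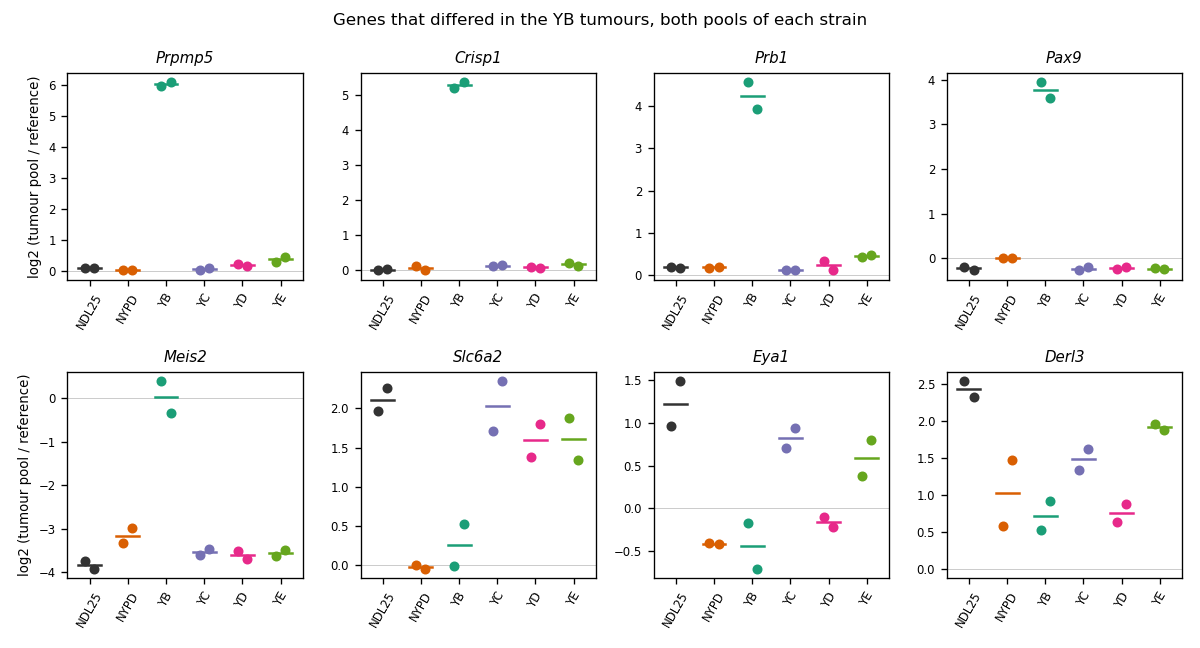
Log2 ratio of tumour pool over reference RNA (y axis) for 8 genes that differed between YB and NDL25, in each of the 6 strains (x axis); points are the 2 pools of a strain and lines their mean. Prpmp5, Crisp1, Prb1, Pax9 and Meis2 rose in YB by log2 3.86 to 5.95, and Slc6a2 and Derl3 fell by 1.85 and 1.72 on the log2 scale.

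Between YB and NDL25, 1109 genes passed limma, 886 higher and 223 lower in YB, 208 of them by 2-fold or more; 4898 had an unadjusted p under 0.05. With session as a block, which leaves these folds as they are because both strains lie in session 2, 361 genes passed, and within session 2 alone 12 did; Prpmp5 had adjusted p = 1.69e-05 with the block. The count was 144 without NDL25 pool 1, 161 without NDL25 pool 2, 592 without either YC pool, 618 without either YD pool and 673 without either YE pool, and 109 genes, 103 higher and 6 lower, were called in every fit that left out 1 pool; it was 515 with the pools numbered 1 of NDL25 and YB left out together, and 12 in a fit of the 2 strains alone.

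YC tumours against NDL25 tumours had 2 genes that passed limma. Slc25a17, a peroxisomal membrane carrier, rose 2.04-fold (log2 1.03 ± 0.08 SE, n = 2 pools per strain, adjusted p = 0.0186), while its other 2 probes gave 0.02 and 1.02. The only other gene that passed, named after its values were seen, was BC006965, at 0.75 ± 0.06 (adjusted p = 0.0186). Antigen presentation genes had a median of 0.46 (camera adjusted p = 2.44e-08): Tap2, a peptide transporter, had 0.63 ± 0.12 (adjusted p = 0.115) and Cd74 1.62 ± 0.37 (0.161). Milk secretion genes had 0.57 (adjusted p = 8.88e-06), with Btn1a1 at 2.0 ± 0.27 (0.066). Endothelial genes had -0.27 (adjusted p = 0.000111), with Kdr, a VEGF receptor, at -0.65 ± 0.16 (0.182). No member of these lists, with 14, 13 and 19 tested genes, passed limma over all genes, against 7 higher, 5 higher and 3 lower adjusted over the list alone, and each list had adjusted p = 0.514 with an estimated correlation.

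Between YC and NDL25, 3223 genes had an unadjusted p under 0.05, where 1418 would be expected with no difference, and the count was 442 with the first array of each pair (192 higher and 250 lower) and 67 with median centring (8 higher and 59 lower). With the second arrays the medians were 0.11 for antigen presentation and 0.10 for milk (adjusted p = 0.118 and 0.341), against 1.11 and 1.29 with the first. The tumour was in Cy5 on the first arrays of YC and in Cy3 on those of NDL25, and the reverse on the second arrays. Fits of the first or second arrays therefore mix a dye difference with the strain difference. The average of a pair cancels it. With session as a block 0 genes passed limma, with Slc25a17 at 0.98 ± 0.09 (adjusted p = 0.167), and within session 2 alone 0, and the lists had medians of 0.49 for antigen presentation, 0.76 for milk and -0.35 for endothelium with adjusted p = 7.74e-09, 0.00019 and 1.32e-05 in the blocked fit; for YC both of these fits rest on pool 1 alone. The count was 0 without either NDL25 pool, without YC pool 1 or without either YD pool, 1 without YC pool 2 or either YE pool, and 36 without either NYPD pool.

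YD tumours against NDL25 had 2 genes that passed limma. Fanca, a gene of the Fanconi anaemia DNA repair complex, fell by 1.03 ± 0.09 on the log2 scale (n = 2 pools per strain, adjusted p = 0.0417), with -0.14 on another probe. Tmed3, a cargo receptor of the secretory pathway named after its values were seen, fell by 0.79 ± 0.06 (adjusted p = 0.0366). Proliferation genes had a median of -0.33 (camera adjusted p = 2.44e-08), with Tyms at -0.82 ± 0.10 (adjusted p = 0.0654) and Mcm7, a replicative helicase subunit, at -0.64 ± 0.10 (0.0849). Adipocyte genes had 0.51 (adjusted p = 1.16e-06), with Adipoq, adiponectin, at 1.22 ± 0.21 (0.105). No member of these lists, with 26 and 14 tested genes, passed limma over all genes, against 5 lower and 4 higher adjusted over the list alone, and both had adjusted p = 0.514 with an estimated correlation. Antigen presentation genes had 0.36 (adjusted p = 0.000113, and adjusted p = 0.514 with an estimated correlation), with 0 of 14 passing, over all genes and adjusted over the list alone. The basal and myoepithelial and the fibroblast lists were also called higher and the endothelial list lower, but none with an estimated correlation. These calls ended in 1, 6 and 3 of 29 alternative settings. The fibroblast median turned to -0.447 with session as a block.

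Between YD and NDL25, 2938 genes had an unadjusted p under 0.05. With session as a block 0 genes passed limma, with Fanca at -1.28 ± 0.24 and so no smaller but less precise, the proliferation and adipocyte medians were -0.10 and 0.13 (adjusted p = 0.539 and 0.191), no longer past the threshold, and antigen presentation had 0.55 (adjusted p = 0.0039), against 0.10 (adjusted p = 0.0511) with the second arrays; the block takes its session term from the difference between the 2 YC pools alone, so strain and session are poorly separated here. The count was 0 without either pool of NDL25, YC, YD or NYPD, 24 without either YB pool and 6 without either YE pool.

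YE tumours against NDL25 had 0 genes that passed limma; 2149 had an unadjusted p under 0.05, and 0 passed with session as a block. Endothelial genes had a median of -0.25 (camera adjusted p = 3.05e-06), with Kdr at -0.57 ± 0.16 (SE, n = 2 pools per strain, adjusted p = 0.433) and Robo4 at -0.46 ± 0.15 (0.494). Antigen presentation genes had 0.27 (adjusted p = 8.18e-05), with Tap2 at 0.40 ± 0.12 (0.473). Skeletal muscle genes had -0.70 (adjusted p = 0.000271), with Myl1, a fast muscle myosin light chain, at -2.02 ± 0.74 (0.579). No member of these lists, with 19, 14 and 13 tested genes, passed limma over all genes or adjusted over the list alone, and they had adjusted p = 0.514, adjusted p = 0.514 and adjusted p = 0.574 with an estimated correlation. Fibroblast and matrix, macrophage, adipocyte and proliferation genes had -0.32, -0.22, 0.26 and -0.16 (adjusted p = 0.00261, 0.00708, 0.00374 and 0.000438; adjusted p = 0.659, 0.659, 0.514 and 0.514 with an estimated correlation), with 0 of 21, 16, 14 and 26 members passing over all genes, and 3 adipocyte genes higher and 2 proliferation genes lower adjusted over the list alone. With session as a block the endothelial, antigen presentation and skeletal muscle medians were -0.58, 0.39 and -3.36 (adjusted p = 9.97e-05, 0.0133 and 5.32e-15), but the block adds 2 times the difference between YC pools 1 and 2, whose median was -1.32 for skeletal muscle, so the move from -0.70 there comes from the YC pools and not from YE; macrophages, adipocytes and proliferation had 0.038, 0.009 and -0.059 (adjusted p = 0.94, 0.873 and 0.884). Without YE pool 2 fibroblasts and macrophages had -0.23 and -0.16 (adjusted p = 0.143 and 0.223), and without NDL25 pool 2 proliferation had -0.068 (adjusted p = 0.39). The count of genes was 1 without YE pool 2 and 2 without either NYPD pool.

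YB tumours against NYPD tumours again carried the salivary-type genes. Prpmp5 rose 64.4-fold (log2 6.01 ± 0.07 SE, n = 2 pools per strain, adjusted p = 2.01e-08), Crisp1 37.7-fold, Prb1 16.7-fold, Dnase1 15.0-fold and Pax9 13.6-fold, with Crisp1, Prb1 and Dnase1 saturated on 1, 2 and 2 of the YB arrays. Saa2 and Glycam1 fell by 2.3 and 2.07 on the log2 scale, and Inmt, a methyltransferase, changed by -2.02 ± 0.40. Fgfr1 and Ctnnd1 had -1.96 and -1.95 on their brightest probes, but 3 other Fgfr1 probes gave -1.70 to 0.29 and the other Ctnnd1 probe 0.01. Of 26 proliferation genes 2 fell, Ttk by 0.82 and the cyclin Ccnb1 by 0.76, with 2 lower adjusted over the list alone (median -0.32, camera adjusted p = 3.05e-06). Of 14 fatty acid synthesis genes 2 fell, the citrate lyase Acly by 0.87, with -0.14 on another probe, and the regulator Srebf1 by 0.84, with 4 lower adjusted over the list alone (median -0.43, adjusted p = 0.000262). Both lists had adjusted p = 0.514 with an estimated correlation, and the proliferation median was -0.06 (adjusted p = 0.099) with the deposited ratios. In all, 1467 genes passed limma, 1156 higher and 311 lower in YB, and 5688 had an unadjusted p under 0.05; the 2 strains lie in different sessions. The count was 906 without either NDL25 pool, 896 without YB pool 2, 780 without either YC pool, 832 without either YD pool, 960 without either YE pool, 869 without NYPD pool 1 (498 higher and 371 lower) and 395 without NYPD pool 2, and 242 genes were called in every one of these fits; a fit of the 2 strains alone called 4.

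YC and YD tumours were each compared with the same 2 NYPD pools, so a common direction is expected from the shared pools. Apobr, an apolipoprotein B receptor, fell by 2.03 ± 0.17 on the log2 scale in YC (n = 2 pools per strain, adjusted p = 0.0235) and changed by -2.02 ± 0.17 in YD (0.034), and Gsr, glutathione reductase, outside the naming rule in YC, changed by -0.98 ± 0.09 and -1.0 ± 0.09. In YC, Slc25a17 rose by 1.31 ± 0.08, with 0.12 and 0.87 on its other probes; BC006965 and C1qtnf12, named after their values were seen, rose by 0.85 and 0.77. In YD, Gjb2, a gap junction protein, fell by 1.52 ± 0.15 and Ccdc28a rose by 1.27 ± 0.13, with 0.33 and 1.14 on other probes. Fibroblast and matrix genes had a median of -0.73 in YC (camera adjusted p = 5.72e-09), with Col6a2 at -0.60 ± 0.14 (adjusted p = 0.199), beside -0.44 for macrophages (adjusted p = 0.000124, and adjusted p = 0.549 with an estimated correlation; 0 of 16 passing, 1 lower adjusted over the list alone), and interferon response genes had 0.93 (adjusted p = 2.44e-08), with Oas1a at 1.06 ± 0.20 (0.135). No member of the fibroblast and interferon lists, with 21 and 20 tested genes, passed limma over all genes, against 3 lower and 2 higher adjusted over the list alone. Proliferation genes had -0.27 in YD (adjusted p = 1.05e-06) and milk genes -0.51 (adjusted p = 8.95e-05), with 0 of 26 and 0 of 13 passing limma over all genes, against 1 and 5 lower adjusted over the list alone. The fibroblast and interferon lists in YC and the proliferation and milk lists in YD had adjusted p = 0.514 with an estimated correlation. In YD fibroblasts had -0.29 and macrophages -0.24 (camera adjusted p = 0.00181 and 0.0451, and adjusted p = 0.659 and 0.723 with an estimated correlation). Of their members 0 of 21 and 0 of 16 passed, and 0 and 2 were lower adjusted over the list alone. Over 28 alternative settings the fibroblast call ended in 2 and the macrophage call in 13, among them the fit without YD pool 2 for both.

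The counts were 5 genes for YC, 3 higher and 2 lower, and 9 for YD, 3 higher and 6 lower, with 2911 and 3068 at an unadjusted p under 0.05, and both contrasts span sessions. With pool number as a block, 2 of the 5 and 5 of the 9 stayed called. Apobr lost its call in 8 of 29 alternative settings in YC and in 9 of 29 in YD. For YC the count was 0 and 1 without YC pools 1 and 2, 15 without either YB pool, 2 without either YD or YE pool, and 302 (61 higher) and 41 (8 higher) without NYPD pools 1 and 2; for YD it was 0 without either pool of YC, YD or YE, 6 without either NDL25 pool, 18 without either YB pool, and 326 and 36 without NYPD pools 1 and 2.

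YE tumours against NYPD tumours had lower Mmp12, Krt19, Glycam1 and Saa2 and higher Serpina3g, Apof and Adh1. Mmp12, macrophage elastase, fell by 3.43 ± 0.50 on the log2 scale (SE, n = 2 pools per strain, adjusted p = 0.0257), Krt19, a luminal keratin, by 3.42 ± 0.64, Glycam1 by 2.63 ± 0.36, Saa2 by 2.51 ± 0.43 and Ndrg1, a hypoxia-induced gene, by 2.29 ± 0.39. Serpina3g, a serine protease inhibitor, rose 6.92-fold (2.79 ± 0.51), Apof, an apolipoprotein, 5.07-fold (2.34 ± 0.25) and Adh1, alcohol dehydrogenase, 4.76-fold (2.25 ± 0.25). Rgcc rose by 1.79, and Sycp3 by 1.77 on its brightest probe with 0.18 on another.

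Of 16 macrophage genes 3 fell, Cd14 by 2.13, the lysozyme Lyz2 by 1.49 and the scavenger receptor Msr1 by 1.03, and 9 were lower adjusted over the list alone (median -0.63, camera adjusted p = 2.86e-05). Of 21 fibroblast and matrix genes 2 fell, the collagens Col6a2 by 0.80 and Col6a3 by 1.51, with -0.07 and -0.04 on other Col6a3 probes, and 16 were lower adjusted over the list alone (median -0.84, adjusted p = 5.72e-09). Of 17 mesenchymal transition genes 2 fell, Zeb2 by 0.81 and Twist1 by 1.03, and 8 were lower adjusted over the list alone (median -0.60, adjusted p = 4e-06). Of 13 milk secretion genes 2 fell, Glycam1 and Wap (log2 -2.63 and -2.28), and 5 were lower adjusted over the list alone (median -0.58, adjusted p = 0.00426, and adjusted p = 0.0506 without NYPD pool 2). Each of these lists had adjusted p = 0.514 with an estimated correlation. The basal and myoepithelial list was also called lower at the preset correlation, though not with an estimated one. Its median ran from -0.628 to -0.386 over 28 alternative settings, and its call ended in 0 of them. In all, 530 genes passed limma, 237 higher and 293 lower in YE, and 5494 had an unadjusted p under 0.05; the 2 strains lie in different sessions. The count was 1 without YE pool 2, 71 without YE pool 1, 193 without either NDL25 pool, 991 without either YB pool, 316 without either YC pool, 228 without either YD pool and 253 without NYPD pool 2, and 0 in a fit of the 2 strains alone. With median centring 606 passed, 152 higher and 454 lower, and without either YB pool 354 were higher and 637 lower.

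**Figure D3:**
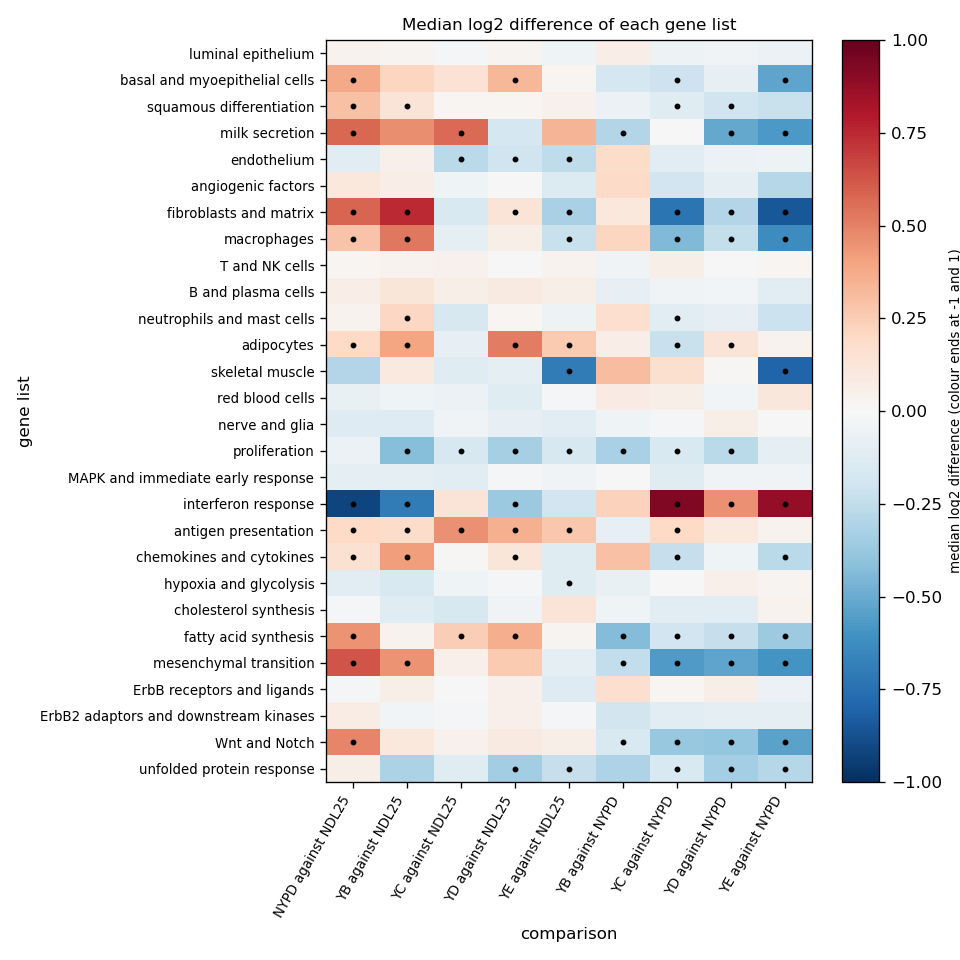
Median log2 difference of each of the 28 gene lists (y axis) in each of the 9 comparisons (x axis), with the colour scale ending at -1 and 1; dots are lists with camera adjusted p under 0.05 at the preset correlation. The interferon list ran from -0.92 in NYPD against NDL25 to 0.93 in YC against NYPD.

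Across all comparisons, camera called 87 of the 252 list tests at the preset correlation, 35 higher and 52 lower, and 0 with an estimated correlation. The luminal epithelium list was not called in any contrast. Antigen presentation was called higher in every contrast against NDL25, in NYPD and YB as in YC, YD and YE. Its call ended in 5 of 28 alternative settings for NYPD and in 9 of 30 for YB. These contrasts share the same NDL25 pools, so a common direction may come from NDL25. The same holds for the endothelial list, called lower in several strains. The proliferation list was called lower against NDL25 in YB, YC, YD and YE, but also against NYPD in YB, YC and YD. Those contrasts hold no NDL25 pool, so the NDL25 pools alone do not account for its direction. They share the NYPD pools, however, and were not called with an estimated correlation.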

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

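Median tumour signal was at least 364.8 over a local background of at most 64, so signal limited few genes: without the filter on dim probes the counts were 900 for the F test and 1108 for YB against NDL25. The number of pools limited more. Of 154 named genes that passed, 154 kept call and direction with Aquantile (which leaves the ratios untouched), with no dim filter and with the filter on all 24 arrays, 149 without background correction, 141 at normexp offset 0, 126 with median centring and 9 in fits of the 2 strains alone. The tumour in Cy5 only, the tumour in Cy3 only, one session only, and the pools numbered 1 of NDL25 and YB left out were chosen after the data were seen. The cause of a change was not tested, except that fewer arrays or pools leave less to test with. In fits of the first or second arrays, dye is also mixed with strain for YC and YD. The first arrays held the tumour in Cy5 for the YC pools and YD pool 1, and in Cy3 for all other pools. The labels do not say whether pools of the same number were handled together, and the fits used for the counts do not pair them. The differences between pools 1 and 2 correlated over 0.1 in 7 of 15 pairs of strains, from -0.172 to 0.712, highest among YC, YD and YE (0.465 to 0.712), so a shared step in part of the strains stays open.

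Counts that moved by over 1.5 times are given by contrast. For NYPD against NDL25 (282) they were 168 with median centring, 48 with an intensity trend and robust estimation, 166 and 139 with the first and second arrays alone, 483 with pool number as a block, 12 with the pools numbered 1 of NDL25 and YB left out, 165 with the deposited log ratios and 0 with the 2 strains alone. For YB against NDL25 (1109) they were 518 and 544 with the first and second arrays, 361 with session as a block, 12 within one session, 515 with those pools left out and 12 with the 2 strains alone. For YC against NDL25 (2) they were 0 with Agilent's processed signals, 67 with median centring, 0 with trend and robust estimation, 442 and 1 with the first and second arrays, 4 and 14 with the tumour in Cy5 and Cy3 only, 5 with pool number, 0 with session as a block, 0 within one session, 1 with those pools left out, 4 with the deposited ratios and 0 with the 2 strains alone. For YD against NDL25 (2) they were 10 at offset 0, 24 with the first array, 9 with the tumour in Cy5 only, 9 with pool number, 1 with those pools left out, and 0 with processed signals, median centring, every probe, trend and robust estimation, the second array, the tumour in Cy3 only, session as a block, the deposited ratios and the 2 strains alone. For YE against NDL25 (0 by limma) it was 1 with every probe and 1 with those pools left out.

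For YB against NYPD (1467) they were 875 with median centring, 513 and 690 with the first and second arrays, 897 with the deposited ratios and 4 with the 2 strains alone. For YC against NYPD (5) they were 12 with processed signals, 3 with median centring, 16 with every probe, 3 with trend and robust estimation, 92 and 104 with the first and second arrays, 9 with the tumour in Cy5 only, 2 with pool number, 9 with those pools left out, 11 with the deposited ratios and 0 with the 2 strains alone. For YD against NYPD (9) they were 21 without background correction, 1 with median centring, 3 with trend and robust estimation, 0 and 1 with the first and second arrays, 44 and 0 with the tumour in Cy5 and Cy3 only, 43 with the deposited ratios and 0 with the 2 strains alone. For YE against NYPD (530) they were 224 with trend and robust estimation, 270 and 350 with the first and second arrays, 210 with the deposited ratios and 0 with the 2 strains alone. The F test (902) gave 587 with the tumour in Cy3 only and 494 with the pools numbered 1 of NDL25 and YB left out. List calls (87) fell to 0 with an estimated correlation, and the pool number block moved no other count by 1.5 times. Among the small counts the balance moved for YD against NYPD (3 higher and 6 lower) to 12 and 9 without background correction and to 24 and 19 with the deposited ratios, and for YC against NDL25 (2 higher) to 8 higher and 59 lower with median centring and to 2 and 2 with the deposited ratios; YC against NYPD (3 higher and 2 lower) had 6 and 6 with processed signals and 3 and 8 with the deposited ratios, and YD against NDL25 (2 lower) 4 higher and 6 lower at offset 0.

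Leaving out each pool in turn gave 159 to 1300 genes for the F test, 0 to 583 for NYPD, 144 to 1211 for YB, 0 to 36 for YC, 0 to 24 for YD and 0 to 2 for YE against NDL25, and 395 to 1812 for YB, 0 to 302 for YC, 0 to 326 for YD and 1 to 991 for YE against NYPD. List calls ran from 67 to 100 and the similarity of pools from 0.187 to 0.269. Some named genes and lists turned direction. With the deposited ratios H2-Aa and Erbb4 in YB against NDL25 were -0.16 and -0.17, and the luminal epithelium list in YB against NYPD had -0.42. With session as a block, which rests on the difference between the 2 YC pools, the medians were -0.52 for skeletal muscle in YC against NDL25 (also -0.52 within one session), -0.45 for fibroblasts, 0.43 for interferon and -0.22 for fatty acid synthesis in YD against NDL25, and 0.038 for macrophages, -0.059 for proliferation, whose test turned, and 0.86 for interferon in YE against NDL25. The antigen presentation list in YC against NYPD was -0.061 with the second array, and fibroblasts in YB against NYPD -0.28 with the pools numbered 1 of NDL25 and YB left out. Leaving out each pool in turn, against NYPD, the median ran from -0.287 to 0.019 for squamous genes in YC, from -0.623 to 0.676 for skeletal muscle in YD and from -0.066 to 0.839 for interferon in YD. Without NYPD pool 2 they were 0.019, 0.676 and -0.041, and interferon in YD was -0.066 without YD pool 2.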

Other observations

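In the first pattern weighed here the test of parotid gland genes, in the second the tests of failed probes, probe effects and a shared handling step, and in the third the test of the extraction session and the values against strains other than NDL25 were chosen only after the result was seen; the other tests were written down before.

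Several further genes differed in YB tumours against NDL25. Krt19, a luminal keratin, rose by log2 3.40 ± 0.64 (SE, n = 2 pools per strain, adjusted p = 0.0317 by limma), and Muc1 by 0.39 ± 0.09, with 1.31 on another probe, while the other 16 luminal genes did not pass and the list's median was 0.03. Sox2, a transcription factor of foregut epithelium among other tissues, rose by 1.55 ± 0.15 and the mucosal chemokine Cxcl17 by 1.73 ± 0.16, and both were called in every fit that left out 1 pool. Blnk, an adaptor of B cell receptor signalling, rose by 1.92 ± 0.19, Asns, asparagine synthetase, by 1.5 ± 0.24 and the immediate early gene Egr2 by 1.35 ± 0.26. The feedback inhibitor Spry4 fell by 1.16 ± 0.18 on its brightest probe, with -0.16 on another. With session as a block Muc1 and Egr2 no longer passed limma (adjusted p = 0.122 and 0.105), while Krt19, Blnk, Asns and Spry4 did. Over 31 alternative settings Krt19, Muc1 and Egr2 lost their calls in 12, 24 and 14. Blnk, Asns and Spry4 lost theirs in 2, 6 and 8.

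Salivary-type genes were high in both YB pools and far lower in the other strains. The barcode series of the slides is argued against by the array of NDL25 pool 2 from the series of YB, on which the 1109 genes called in YB moved with a slope of 0.013 ± 0.004 on their YB difference. Those genes were chosen by a contrast that includes this array, which favours genes that did not move on it and lowers the slope. The ± value treats genes on 1 array as independent. For mature salivary gland tissue in the pools, a list of 20 secretory salivary genes was used, 17 of them tested and 1 also in a fixed list. Its median in YB over the other strains was 0.304 (quartiles -0.009 and 0.603), below the limit set beforehand for counting against such tissue. Smr2 and Dcpp1, abundant in mature glands, had -0.01 and -0.16, and 2 of the 17 were higher by 1 or more in both pools. Part of the list did rise, with Amy1, Cst10 and Pip at 2.84, 3.42 and 2.48 (Pip 0.997 and 3.97 in the 2 pools). Against NDL25, where limma was run, Amy1, Cst10, Lpo and Dmbt1 passed. The median lay above 100% of 10000 random lists, which were matched on intensity but not for genes that vary together. The median alone falls under that limit, but the upper quartile of 0.603 and the members that rose leave the test undecided. Mature gland tissue is therefore neither shown nor excluded. Parotid gland cells in the dissected YB tissue remain possible and may account for the pattern, since 8 parotid genes had a median of 3.666, but most of these were known to be high when the list was written, and Car6, another abundant parotid product, had -0.22. A change in the tumour cells themselves, tied to the YB receptor or to the founder line, also stays open and was not tested.

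The brightest Erbb2 probe was low in pool 1 of NDL25 and of YB. A lower share of tumour epithelium is argued against by the 18 luminal genes, whose median difference between these pools and the other pools of the same strains was 0.006 (SD 0.294). For probes that failed on the slides, the 60 genes lower by 1 or more in both pools were examined in each channel. They differed by a median of -0.091 in the reference channel and -1.547 in the tumour channel. These genes were chosen for a lower ratio of tumour over reference. That choice works against a lower reference channel, so the test cannot exclude failed probes. A handling step shared by the pools of 1 number stays open: the same 60 probes differed between pools 1 and 2 by medians of -0.151 in YC, 0.105 in YD and 0.018 in YE, but by -0.506 in NYPD, where 53 were lower (-0.108 for the mean of the 4 strains). The gap may be an effect of single probes rather than of genes: 24 other probes of 15 of these genes had a median of -0.05 (-0.062 with 1 value per gene) where the 15 brightest probes had -1.421, although 4 of the 24 were lower by 1 or more. For Erbb2 itself this stays open, because which part of the gene each probe reads could not be checked. Its other 2 probes had log2 ratios of -0.01 to 1.03 over the pools, below every value of the brightest. Levels of different probes cannot decide the question.

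Saa2 and 5 of 13 milk secretion genes were higher in NYPD than in NDL25, but the milk list's median over NDL25 was 0.57 in YC as in NYPD, and -0.005 in YC against NYPD. An involution-like and acute phase state is a candidate explanation for the acute phase genes only. A list of 18 such genes was used, 17 tested without those already named and 1 of them also in a fixed list. None of the tested genes belongs to the milk secretion list, so they do not bear on the higher milk genes. The median of the involution list was 0.804 over NDL25 and 0.496 over the mean of the other 5 strains. Each lay above 100% of 10000 random lists of like intensity. The random lists were matched on intensity alone. The share therefore cannot say how unusual such a median is for genes that vary together. The involution list does not set NYPD apart from YB, which had 0.736 over NDL25 and 0.039 over NYPD, and the macrophage list moved beside it, with medians over NDL25 of 0.286 in NYPD, 0.526 in YB and -0.222 in YE (camera adjusted p = 0.0048, 1.46e-05 and 0.00708; adjusted p = 0.659, 0.514 and 0.659 with an estimated correlation) where the involution list had -0.046 in YE. Of its members only Lbp, at 0.88 over NDL25 against 0.92 in YB, and Ctsb, at 0.71, passed limma in NYPD; Saa1 and Saa3 had 2.75 and 2.71 (adjusted p = 0.0786 and 0.0532), and Igfbp5, an involution gene, had -0.74. The extraction session cannot be told apart from the strain, because 0 arrays of other strains were read in the session of NYPD.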
